A study of Dichomitus squalens with 16 samples.

How the data were processed

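Dichomitus squalens LYAD-421 SS1, a white-rot fungus that grows on wood and breaks down its lignin and polysaccharides, was cultured at 28 °C. After a preculture of 4 days, the cultures held 1 g of sawdust from spruce or aspen wood, or of powder from wheat bran or from the hulls of cotton seeds, in 100 ml of low-nitrogen medium with 6.8 mM glycerol. Mycelium was sampled on day 9 and day 16. Each of the 8 groups (4 substrates at 2 times) has 2 libraries, 16 in all. RNA was extracted by a CTAB method with column purification, and mRNA libraries were made and sequenced by Illumina protocols. The labels do not state whether the libraries keep the strand, so overlapping genes cannot be told apart. They also do not say that the 2 replicates of a group were separate cultures, so the spread behind each p may be technical only.

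The deposited values are raw unique read counts per gene model and RPKM (reads scaled to gene model length and to the unique reads of the library), both computed by the authors. The aligner, the counting tool and the genome build are not given in the sources used here. Checks on the values showed that the read counts are whole numbers that sum to the stated total of each library. RPKM recomputed from reads, total and length equalled the deposited RPKM. Genes missing from a library were taken as 0 reads. Across the libraries 11410 genes had reads, of which 10589 had reads in every library. Gene names are the descriptions in the files, which the authors took from a protein database search. They were informative for 4452 genes and not for 6958. Identifiers are locus tags built from the protein number, and 11371 of the 11410 matched the reference list of locus tags. Genomic positions were not used beyond the order of neighbouring genes, and no coordinates are given.

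Differential expression was tested on the read counts with edgeR 4.0.16 in R 4.3.3. Genes with low counts were removed with filterByExpr (minimum count 10, minimum total 15), which left 10584 genes and took out 826. Libraries were scaled by TMM, and a quasi-likelihood model with robust dispersion and 1 mean per group was fitted to all 16 libraries, with 8 residual degrees of freedom. The common biological coefficient of variation was 0.0982. The 13 contrasts were tested by the two-sided quasi-likelihood F-test. The first were wood (mean of spruce and aspen) against non-woody substrates (mean of wheat bran and cotton seed hulls), spruce against aspen, and wheat bran against cotton seed hulls, each on day 9 and on day 16. The others were day 16 against day 9 on each substrate, and the differences of these day effects between wood and non-woody substrates, between spruce and aspen, and between wheat bran and cotton seed hulls. Adjusted p values of genes are Benjamini-Hochberg values over the 10584 genes from this edgeR test, with a threshold of 0.05. A positive log2 fold change means higher on the side named before "against", or higher on day 16.

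Gene groups were 37 lists built from patterns in the descriptions. They were class II peroxidases, laccases and multicopper oxidases, copper radical oxidases, GMC oxidoreductases, other peroxidases, cellobiohydrolases, endoglucanases, lytic polysaccharide monooxygenases, cellobiose dehydrogenase, beta-glucosidases, carbohydrate-binding module proteins, xylanases, xylan side-chain enzymes, mannanases, pectinases, amylases, chitin and fungal wall enzymes, hydrophobins, secreted proteases, lipases and esterases, cytochrome P450 proteins, glutathione S-transferases, sugar transporters, peptide and amino acid transport, nitrogen uptake, oxalate and formate enzymes, pentose catabolism, the glyoxylate cycle, fatty acid oxidation, glycolysis, ribosomal proteins, the proteasome, heat shock proteins and chaperones, DNA replication and histones, autophagy, mitochondrially encoded genes, and housekeeping genes. The 3 lists with no gene by description were carbohydrate-binding module proteins, autophagy and mitochondrially encoded genes. The 31 lists with at least 3 tested members were tested against all other genes with camera (limma 3.58.1, preset correlation 0.01), Benjamini-Hochberg adjusted over the 403 tests of lists and contrasts. Smaller lists are given as counts. The comparisons, the tests, the lists, the rule for named genes and all alternatives except those stated as added were fixed before the data were examined.

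Genes were named by a rule: past the threshold, RPKM of the compared libraries not overlapping, and a mean RPKM of at least 10 on the higher side. Among these, the rule took the genes with an informative description and the largest changes: up to 10 in each direction for wood against non-woody substrates, 6 for the contrasts between 2 substrates, 3 for each day contrast, and 2 for differences of day effects, where overlap was not asked. It also took the largest change in each direction without a description, the 2 members with the highest mean RPKM of each called list, and the 2 highest of the class II peroxidases, laccases, cellobiohydrolases, lytic polysaccharide monooxygenases, xylanases, mannanases, pectinases and amylases whatever their result. It named 134 genes.

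The alternatives were DESeq2 size factors, library size alone, no filter on low counts, the DESeq2 1.42.0 Wald test, limma on log2 of the deposited RPKM plus 1 or plus 0.1, the replicate number as a block, a 2-fold minimum, a fit with only the compared groups, and leaving out each library in turn. An arm left with 1 library is then assumed to vary like the other groups. Lists were also tested with an estimated correlation, without their most changed member, and with fry. Fry tests a list against no change and not against other genes, and ranges over alternatives include its values. For wood against non-woody substrates, genes with RPKM not overlapping between the sides were counted and the 2 other pairings of the substrates were tested. Counts within 1.5 times of the reported count were read as stable. Alternatives added after seeing the data were 7 further lists and a day 16 wood contrast without the day 9 wood groups. Simulated data had 200 changed genes, fewer than called here, so rates may not carry over. The test recovered 58, 96 and 98 % of 1.5-, 2- and 4-fold changes for wood on day 9, with 6.38 % false calls. For the difference of day effects between wheat bran and cotton seed hulls it was 14, 48 and 86 %, with 6.3 %. Where a named gene had reads on the lower side, but at most 3 per library, the ratio of summed reads is given with its 95 % exact binomial interval, and where 0 reads, a bound against 3 reads per library. These intervals and bounds cover counting error only. No deposited sample or column was left out. The exoproteome part of the study was not used here.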

Results

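The transcripts of Dichomitus squalens were measured in mycelium grown with wood (spruce or aspen sawdust) or non-woody plant material (wheat bran or cotton seed hulls) for 9 or 16 days, with 2 libraries in each of the 8 groups. Group means of unique reads per library lay between 8086856 ± 145560 (SD, n = 2) for spruce on day 16 and 8636932 ± 297801 for cotton seed hulls on day 9. Replicates correlated across genes with Pearson's r of 0.989 to 0.996, although genes are not independent replicates. Their spread relative to counting error was widest in the day 9 wood groups, with a chi-square per degree of freedom of 30.7 for aspen and 28.1 for spruce against 1.69 to 11.9 in the other groups.

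Expression levels are mean RPKM ± SD (n = 2 libraries), changes are log2 fold changes ± standard error, and adjusted p values and counts of genes are from the edgeR quasi-likelihood test with Benjamini-Hochberg adjustment. For gene lists, the median log2 fold change of the tested members is given with the adjusted p of the list test, and members are those tested. Counts of members adjusted over the list alone follow the words list alone where they differ from those over all genes. Of 403 list tests, 34 passed the threshold with both the preset and an estimated correlation, and 94 with the preset correlation alone. In parentheses and ranges, estimated stands before the adjusted p with an estimated correlation, and highest before the highest over all alternatives, where above both. Those 34 lie among the tests of cellobiohydrolases, endoglucanases, lytic polysaccharide monooxygenases, mannanases, pectinases, chitin and fungal wall enzymes, hydrophobins and proteasome genes, and 33 of them kept the call in every alternative run. The other, mannanases for the day effect on wood minus that on non-woody substrates, lost it with limma on RPKM (adjusted p = 0.0869 and 0.0873 with 1 and 0.1 added). Composition scaling sets the centre of each comparison. With library size alone the median of all genes moved to 0.31 and 0.51 for wood against non-woody substrates on days 9 and 16, 0.22 for spruce against aspen on day 9, and 0.25 and 0.48 for wheat bran against cotton seed hulls. It moved to 0.17 for the day effect on aspen, -0.22 on cotton seed hulls, and 0.22, -0.14 and 0.22 for the differences of day effects. As reported these medians lay between -0.02 and 0.03, and all changes are relative to them.

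The woods and non-woody substrates were compared on day 9. As p rests on replicate spread, it does not cover wood as a class. Enzymes that cut cellulose, mannan and pectin were lower on wood as lists. Cellobiohydrolase II (DICSQDRAFT_152125), which releases cellobiose from the ends of cellulose chains, reached 6.44 ± 0.96 RPKM on spruce, 3.13 ± 0.0979 on aspen, 268 ± 42.4 on wheat bran and 805 ± 71.3 on cotton seed hulls (log2 fold change -6.96 ± 0.15, adjusted p = 1.14e-14). The cellobiohydrolases had 1 of 6 members higher and 5 lower (median -3.23, adjusted p = 2.01e-05, estimated 0.117). This list includes oligoxyloglucan reducing-end-specific enzymes, which act on xyloglucan. Endoglucanases, which cut inside cellulose chains, had 1 of 10 members higher and 9 lower (median -3.07, adjusted p = 0.000211, estimated 0.0358). The list's most abundant members are barwin-like proteins such as DICSQDRAFT_49028 (-0.90 ± 0.09). Mannanases had 3 of 3 members lower (median -1.30, adjusted p = 6.83e-05, estimated 0.03), led by the CEL4a mannanase (DICSQDRAFT_132822, -4.55 ± 0.09). Pectinases had 9 of 10 members lower (median -1.46, adjusted p = 0.000528, estimated 0.122), with endo-polygalacturonase PG1 (DICSQDRAFT_154984) at -5.83 ± 0.28. Xylanase C (DICSQDRAFT_133555) was at 98.6 ± 1.38 RPKM on cotton seed hulls and 50.6 ± 6 on wheat bran against 2.02 ± 0.476 on spruce and 1.2 ± 0.189 on aspen (-5.77 ± 0.10).

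**Figure D1:**
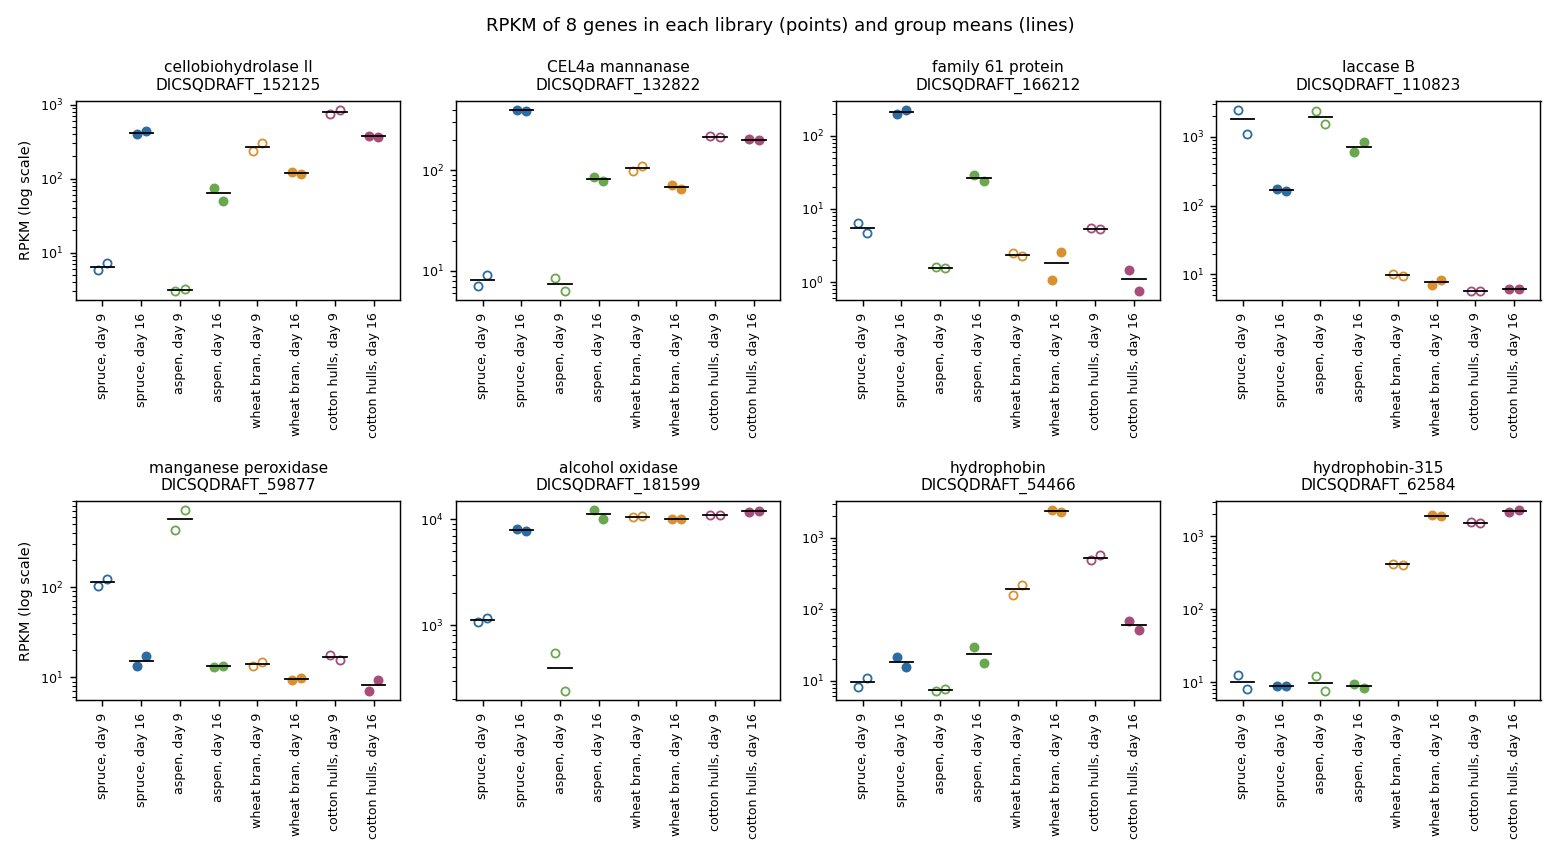
RPKM of 8 genes in every library on a log axis, by substrate, with open points for day 9, filled points for day 16 and lines for the group means. Cellobiohydrolase II lies at 6.44 ± 0.96 on spruce on day 9 and at 416 ± 30.1 on day 16, while laccase B lies at 1806 ± 979 and 169 ± 6.7.

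Oxidative enzymes of lignin breakdown were mixed on day 9. Laccases and multicopper oxidases, copper enzymes that oxidise phenols, had 8 of 12 members higher and 2 lower (median 2.07, adjusted p = 0.0023, estimated 0.21). Laccase B (DICSQDRAFT_110823) reached 1806 ± 979 RPKM on spruce, 1949 ± 591 on aspen, 9.87 ± 0.404 on wheat bran and 5.82 ± 0.0115 on cotton seed hulls (log2 fold change 7.67 ± 0.32, adjusted p = 8.77e-09), and laccases DICSQDRAFT_169869 (7.29 ± 0.37) and DICSQDRAFT_176907 (6.38 ± 0.13) were higher too. A manganese peroxidase (DICSQDRAFT_59877), a heme enzyme that oxidises manganese ions that in turn attack lignin, was higher at 114 ± 15.1 RPKM on spruce and 575 ± 207 on aspen (3.79 ± 0.19). Another (DICSQDRAFT_141471) was lower (-4.76 ± 0.18), and the class II peroxidases as a list had 3 of 12 members higher and 4 lower (median 0.12, adjusted p = 0.83). Glyoxal oxidase (DICSQDRAFT_167685), a source of hydrogen peroxide, was lower at -8.48 ± 0.18. GMC oxidoreductases, flavoenzymes that include alcohol and aryl-alcohol oxidases, had 18 of 29 members higher and 6 lower (median 0.88, adjusted p = 0.028, estimated 0.118, highest 0.17). The most abundant of them, alcohol oxidase DICSQDRAFT_181599, was lower on wood (-4.30 ± 0.19). The DyP-type peroxidase DICSQDRAFT_150405, chosen after its values were seen, was among the most abundant transcripts on day 9 wood at 9398 ± 2787 RPKM on spruce and 7051 ± 1473 on aspen, against 909 ± 43.8 on wheat bran and 127 ± 7.28 on cotton seed hulls (4.30 ± 0.13).

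Hydrophobins and wall enzymes were lower on wood on day 9, and cytochrome P450, ribosomal and proteasome genes were higher. Hydrophobins, small secreted proteins that coat fungal surfaces, had 1 of 15 members higher and 9 lower (median -1, adjusted p = 0.00161, estimated 0.117), and hydrophobin-315 (DICSQDRAFT_62584) was at -6.60 ± 0.10. Chitin and fungal wall enzymes had 3 of 21 members higher and 17 lower (median -1.28, adjusted p = 5.04e-06, estimated 0.128), among them chitin synthase DICSQDRAFT_165065 (-1.22 ± 0.08). A secreted triacylglycerol lipase (DICSQDRAFT_137620) was lower at -4.80 ± 0.16. Lipases and esterases with 12 of 32 higher and 16 lower also passed (median -0.37, adjusted p = 0.007, estimated 0.24). Cytochrome P450 proteins, which oxidise small molecules such as aromatic compounds, had 76 of 156 members higher and 35 lower (median 0.40, adjusted p = 0.00923, estimated 0.354), with DICSQDRAFT_168992 at 4.08 ± 0.10. Ribosomal proteins had 64 of 92 members higher and 12 lower (median 0.67, adjusted p = 1.45e-05, estimated 0.381). Proteasome genes had 17 of 17 members higher (median 1.47, adjusted p = 2.26e-13, estimated 0.03), with the assembly factor UMP1 (DICSQDRAFT_113392) at 1.30 ± 0.07. Among the largest changes upward were norsolorinic acid reductase (DICSQDRAFT_66487, 8.83 ± 0.34), UbiA prenyltransferase (DICSQDRAFT_81420, 8.65 ± 0.75), a nitroreductase (DICSQDRAFT_69755, 8.04 ± 0.83) and a carbonic anhydrase (DICSQDRAFT_180719, 7.15 ± 0.20). A glycopeptide gene (DICSQDRAFT_148664) was higher 392-fold by reads (counting interval 108 to 3244). Among the genes lower on wood were also an FAD-dependent oxidoreductase (DICSQDRAFT_157633, -8.27 ± 0.23), a metalloprotease (DICSQDRAFT_131350, -6.25 ± 0.24) and a thaumatin-like protein (DICSQDRAFT_152858, -5.92 ± 0.20).

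On day 9, 7574 of 10584 genes passed the threshold, 3959 higher and 3615 lower, and 2952 of them were at least 2-fold. Of the genes called, 5089 had RPKM ranges that did not overlap between the 4 wood and 4 non-woody libraries, a state of 52.2 % of all genes. Chance gives 2.86 % for independent libraries and 33.3 % if replicates fall together. The call of GMC oxidoreductases was lost without aspen day 9 replicate 1 (adjusted p = 0.0582), with adjusted p from 7.27e-08 to 0.17 over all alternatives of this list. With library size alone 5381 genes were higher and 2455 lower, so that 68.7 % of the genes called were higher instead of 52.3 %.

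On day 16 cellulose enzyme lists, unlike hydrophobins and wall enzymes, were not lower on wood. On aspen cellobiohydrolase II still was lower. Hydrophobins had 2 of 15 members higher and 10 lower (list alone 3 higher and 10 lower, median -1.06, adjusted p = 1.6e-06, estimated 0.03). Hydrophobin-315 was at 8.8 ± 0.106 RPKM on spruce and 8.72 ± 0.776 on aspen against 1916 ± 42.5 on wheat bran and 2229 ± 96.3 on cotton seed hulls (log2 fold change -8.36 ± 0.11, adjusted p = 3.23e-18). Chitin and fungal wall enzymes had 18 of 21 members lower (list alone 19 lower, median -1.26, adjusted p = 5.36e-12, estimated 0.03), with a family 16 glycoside hydrolase (DICSQDRAFT_69888) at -1.51 ± 0.07. Lytic polysaccharide monooxygenases, copper enzymes that cut crystalline cellulose by oxidation, had 3 of 3 members higher (median 1.79, adjusted p = 0.000527, estimated 0.131). Member DICSQDRAFT_166212 reached 211 ± 22.8 RPKM on spruce, 26.5 ± 3.86 on aspen, 1.82 ± 1.08 on wheat bran and 1.11 ± 0.486 on cotton seed hulls (5.22 ± 0.18). Cellobiohydrolases had 4 of 6 members higher and 1 lower (median 0.83, adjusted p = 0.181), and endoglucanases 6 of 10 higher and 2 lower (median 0.50, adjusted p = 0.145). Laccases and multicopper oxidases had 8 of 12 members higher and 3 lower (median 0.88, adjusted p = 0.037, estimated 0.391, highest 0.631), with laccase B at 5.18 ± 0.29. Manganese peroxidase DICSQDRAFT_59877 was at 0.19 ± 0.22, adjusted p = 0.484. Cytochrome P450 proteins with 76 of 156 higher and 27 lower, proteasome genes with 14 of 17 higher and 1 lower, and ribosomal proteins with 68 of 92 higher and 5 lower (list alone 69 higher and 5 lower) also passed. Across these 3 lists medians ran from 0.34 to 0.48 and adjusted p from 3.74e-08 to 0.0247, estimated 0.236 to 0.391. The call of laccases and multicopper oxidases was lost with library size alone (adjusted p = 0.0899), without cotton seed hulls day 16 replicate 1 (0.0829), cotton seed hulls day 16 replicate 2 (0.0688), wheat bran day 16 replicate 1 (0.0769) and wheat bran day 16 replicate 2 (0.0762), with adjusted p from 9.23e-05 to 0.631 over all alternatives of this list.

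On day 16 glyoxylate dehydrogenase (DICSQDRAFT_183166, -4.56 ± 0.16), which makes oxalate from glyoxylate, a phosphoenolpyruvate/pyruvate-domain protein (DICSQDRAFT_111644, -5.29 ± 0.12) and oxalate decarboxylase (DICSQDRAFT_163336, -4.44 ± 0.40), which breaks oxalate down to formate, were lower on wood. Glyoxal oxidase was lower as well (-6.47 ± 0.16). Higher on wood were norsolorinic acid reductase (6.45 ± 0.34), cytochrome P450 DICSQDRAFT_172711 (5.96 ± 0.28), a sterol 14 alpha-demethylase (DICSQDRAFT_147974, 4.92 ± 0.20), a sulfate permease (DICSQDRAFT_146123, 5.18 ± 0.17) and a calcium ATPase (DICSQDRAFT_156959, 4.93 ± 0.15).

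On day 16, 6320 genes passed the threshold, 3140 higher and 3180 lower, and 1665 of them were at least 2-fold. Both days shared 1971 genes higher on wood, where 1174.5 would fall together by chance, and 2117 lower, against 1086.1, while 851 changed in opposite directions. Library size alone gave 7036 higher and 1137 lower, or 86.1 % of the genes called higher instead of 49.7 %. By RPKM, scaled by library size alone, 4564 genes lay higher on wood without overlap and 697 lower (49.7 %). Of these 3497 were called, and chance is as on day 9.

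Spruce and aspen, a softwood and a hardwood, were compared. On day 9 laccase DICSQDRAFT_176907 was lower on spruce (264 ± 7.24 RPKM) than on aspen (1226 ± 167; log2 fold change -2.43 ± 0.15, adjusted p = 8.9e-08). Laccase B did not pass the test (-0.32 ± 0.32, adjusted p = 0.542). Laccases and multicopper oxidases had 1 of 12 members higher and 4 lower (median -0.28, adjusted p = 0.000779, estimated 0.167). Higher on spruce were cellobiohydrolase I (DICSQDRAFT_96488, 1.40 ± 0.24), a mannitol-1-phosphate 5-dehydrogenase (DICSQDRAFT_140659, 1.91 ± 0.19), a metalloprotease (DICSQDRAFT_156505, 2.58 ± 0.31) and a family S53 protease (DICSQDRAFT_182861, 2.66 ± 0.25), and lower was an FAD-binding protein (DICSQDRAFT_162938, -3.65 ± 0.38). Cellobiohydrolases had 2 of 6 members higher (median 0.70, adjusted p = 0.037, estimated 0.391).

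Proteasome genes with 14 of 17 lower (list alone 16 lower), hydrophobins with 4 of 15 lower, and chitin and fungal wall enzymes with 7 of 21 lower also passed. So did glycolysis genes with 4 of 24 lower, secreted proteases with 2 of 42 higher and 14 lower (list alone 3 higher and 15 lower) and a median of -0.18, or 0.035 by library size alone, and GMC oxidoreductases with 6 of 29 higher and 10 lower (list alone 7 higher and 13 lower). Across these 6 lists medians ran from -0.43 to -0.18 and adjusted p from 1.21e-08 to 0.0361, estimated 0.0558 to 0.324. The secreted proteases take in some intracellular proteins by their names, such as aspartyl-tRNA synthetase. The call of cellobiohydrolases was lost with library size alone (adjusted p = 0.0502), without aspen day 9 replicate 1 (0.183) and spruce day 9 replicate 2 (0.0716). The call of GMC oxidoreductases was lost without aspen day 9 replicate 1 (adjusted p = 0.0708). The call of glycolysis genes was lost without aspen day 9 replicate 1 (adjusted p = 0.118) and spruce day 9 replicate 2 (0.0716). The call of laccases and multicopper oxidases was lost without spruce day 9 replicate 2 (adjusted p = 0.0716). The call of hydrophobins was lost without spruce day 9 replicate 2 (adjusted p = 0.115), with adjusted p from 1.24e-07 to 0.391 over all alternatives of these 5 lists.

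For spruce against aspen on day 9, 2265 genes passed the threshold, 874 higher and 1391 lower, and 438 of them were at least 2-fold. The count fell without aspen day 9 replicate 2 and was 376 in a fit without the groups of less spread, on which p above also rests. Library size alone gave 2779 higher and 731 lower.

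By day 16 cellulose-degrading genes were higher on spruce and laccases lower. Cellobiohydrolase II reached 416 ± 30.1 RPKM on spruce and 62.9 ± 18.1 on aspen (log2 fold change 2.64 ± 0.16, adjusted p = 9.34e-08), and cellobiohydrolase I genes DICSQDRAFT_96488 (3.11 ± 0.16) and DICSQDRAFT_131122 (4.12 ± 0.34) were higher too. Cellobiohydrolases had 5 of 6 members higher (median 2.81, adjusted p = 6.07e-30, estimated 0.00244). Lytic polysaccharide monooxygenases had 3 of 3 members higher (median 2.90, adjusted p = 1.43e-24, estimated 0.00244), with DICSQDRAFT_140533 at 3.48 ± 0.19 and DICSQDRAFT_166212 at 2.90 ± 0.15. Endoglucanases had 7 of 10 members higher and 2 lower (median 0.96, adjusted p = 2.59e-15, estimated 0.00244). The CEL4a mannanase was higher (2.19 ± 0.10). Pectinases with 5 of 10 higher (list alone 6 higher and 1 lower), mannanases with 1 of 3 higher and 1 lower, and xylan side-chain enzymes with 3 of 8 higher and 1 lower (list alone 3 higher and 2 lower) also passed. Across these 3 lists medians ran from 0.06 to 0.44 and adjusted p from 0.00154 to 0.00191, estimated 0.0607 to 0.132, highest 0.385. Laccases and multicopper oxidases had 6 of 12 members lower (list alone 7 lower, median -0.85, adjusted p = 1.42e-06, estimated 0.0608), with laccase B at 169 ± 6.7 RPKM on spruce and 724 ± 158 on aspen (-2.19 ± 0.34).

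Glyoxal oxidase was lower on spruce on day 16 (-2.67 ± 0.21). Copper radical oxidases with 1 of 9 higher and 3 lower, peptide and amino acid transport with 3 of 39 higher and 13 lower, and chitin and fungal wall enzymes with 1 of 21 higher and 8 lower (list alone 1 higher and 10 lower) also passed. So did ribosomal proteins with 28 of 92 higher and 4 lower (list alone 29 higher and 4 lower) and proteasome genes with 12 of 17 higher (list alone 13 higher). Across these 5 lists medians ran from -0.31 to 0.34 and adjusted p from 0.000137 to 0.0477, estimated 0.164 to 0.615. The call of ribosomal proteins was lost without aspen day 16 replicate 1 (adjusted p = 0.131). The call of copper radical oxidases was lost without spruce day 16 replicate 1 (adjusted p = 0.0529) and spruce day 16 replicate 2 (0.0721), with adjusted p from 5.28e-06 to 0.615 over all alternatives of these 2 lists. Single genes with large changes were agmatinase (DICSQDRAFT_71040, -2.93 ± 0.20) and metalloprotease DICSQDRAFT_156505 (4.46 ± 0.29).

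For spruce against aspen on day 16, 2483 genes passed the threshold, 1214 higher and 1269 lower, and 507 of them were at least 2-fold. On both days 218 genes were higher on spruce (100.25 by chance) and 292 lower (166.78). Opposite changes numbered 309, their chance value not computed. Across genes, which are not independent, changes of the 2 days hardly correlated (Pearson's r = 0.0403). The count was 1343 without aspen day 16 replicate 2, 1620 without spruce day 16 replicate 1 and 1306 without spruce day 16 replicate 2.

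Wheat bran and cotton seed hulls, both non-woody, differ in their polysaccharides. On day 9 cellulose and mannan enzymes were lower on wheat bran as lists. Endo-polygalacturonase PG1, which cuts the pectin backbone, reached 9.46 ± 1.4 RPKM on wheat bran and 367 ± 1.4 on cotton seed hulls (log2 fold change -5.51 ± 0.28, adjusted p = 1.81e-07). Cellobiohydrolases had 4 of 6 members lower (median -1.56, adjusted p = 9.87e-08, estimated 0.0532), with cellobiohydrolase II at -1.82 ± 0.15. Endoglucanases had 1 of 10 members higher and 6 lower (list alone 1 higher and 7 lower, median -1.07, adjusted p = 5.24e-08, estimated 0.0125), with an endo-beta-1,4-glucanase (DICSQDRAFT_147873) at -3.63 ± 0.21. Mannanases had 2 of 3 members lower (median -1.14, adjusted p = 0.000281, estimated 0.0387). Lytic polysaccharide monooxygenase DICSQDRAFT_108020 was lower (-2.15 ± 0.14). Pectinases had 2 of 10 members higher and 3 lower (median 0.11, adjusted p = 0.0261, estimated 0.277, highest 0.604), and here the median is positive while the mean of -0.71 and the test are negative.

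Hydrophobins had 1 of 15 members higher and 4 lower (median -0.31, adjusted p = 0.00405, estimated 0.131), with hydrophobin-315 at -2.14 ± 0.10. Lytic polysaccharide monooxygenases with 3 of 3 lower, chitin and fungal wall enzymes with 3 of 21 higher and 15 lower (list alone 3 higher and 16 lower), and copper radical oxidases with 3 of 9 lower (list alone 1 higher and 3 lower) and a median of -0.18, or 0.05 by library size alone, also passed. So did cytochrome P450 proteins with 49 of 156 higher and 15 lower (list alone 54 higher and 15 lower) and ribosomal proteins with 52 of 92 higher and 1 lower (list alone 55 higher and 1 lower). Across these 5 lists medians ran from -1.41 to 0.39 and adjusted p from 1.13e-07 to 0.0343, estimated 0.0733 to 0.317. The call of copper radical oxidases was lost without wheat bran day 9 replicate 2 (adjusted p = 0.0587). The call of pectinases was lost without wheat bran day 9 replicate 2 (adjusted p = 0.125), with adjusted p from 7.15e-06 to 0.604 over all alternatives of these 2 lists. Among single genes a ricin B-like lectin (DICSQDRAFT_172726), a carbohydrate-binding protein, was higher on wheat bran 1851-fold by reads (counting interval 793 to 5701). A calcium ATPase (DICSQDRAFT_156959, 4.27 ± 0.23) and a sodium-potassium ATPase (DICSQDRAFT_47382, 4.06 ± 0.21), both ion pumps, were higher as well.

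For wheat bran against cotton seed hulls on day 9, 3574 genes passed the threshold, 1611 higher and 1963 lower, and 817 of them were at least 2-fold. The count was 2239 without cotton seed hulls day 9 replicate 2.

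On day 16 the hydrophobins as a list had turned to the other direction. Fungal hydrophobin DICSQDRAFT_54466 reached 2355 ± 114 RPKM on wheat bran and 59.6 ± 11.9 on cotton seed hulls (log2 fold change 4.83 ± 0.22, adjusted p = 2.08e-08), and DICSQDRAFT_55052 (6.26 ± 0.52), DICSQDRAFT_62768 (5.32 ± 0.32) and DICSQDRAFT_167756 (3.12 ± 0.28) were also higher on wheat bran. Hydrophobins had 8 of 15 members higher and 1 lower (list alone 9 higher and 1 lower, median 1.77, adjusted p = 3.19e-12, estimated 0.0108, highest 0.0214). Lytic polysaccharide monooxygenases did not pass, with 2 of 3 members lower (median -1.30, adjusted p = 0.0618). Mannanases had 3 of 3 members lower (median -2.04, adjusted p = 1.74e-13, estimated 0.00275). Endoglucanases had 8 of 10 members lower (list alone 1 higher and 8 lower, median -1.68, adjusted p = 9.3e-16, estimated 0.00244). Cellobiohydrolases had 5 of 6 members lower (median -1.60, adjusted p = 1.77e-06, estimated 0.0701). Pectinases had 7 of 10 members lower (median -0.80, adjusted p = 4.88e-08, estimated 0.0298). Chitin and fungal wall enzymes had 13 of 21 members lower (list alone 15 lower, median -0.85, adjusted p = 4.75e-12, estimated 0.0339).

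The abundant small heat shock protein DICSQDRAFT_109568 (2.04 ± 0.26) and ammonium transporter DICSQDRAFT_112666 (0.93 ± 0.09) were higher on wheat bran on day 16. Heat shock proteins and chaperones with 1 of 25 higher and 11 lower and a median of -0.46, or 0.016 by library size alone, nitrogen uptake with 3 of 8 higher, and ribosomal proteins with 35 of 92 higher and 3 lower (list alone 40 higher and 3 lower) also passed. Across these 3 lists medians ran from -0.46 to 0.21 and adjusted p from 0.000374 to 0.037, estimated 0.284 to 0.46. The call of nitrogen uptake was lost without cotton seed hulls day 16 replicate 2 (adjusted p = 0.0876), with adjusted p from 0.000312 to 0.285 over all alternatives of this list. The ricin B-like lectin was higher on wheat bran 468-fold by reads (counting interval 129 to 3867).

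For wheat bran against cotton seed hulls on day 16, 3320 genes passed the threshold, 1381 higher and 1939 lower, and 847 of them were at least 2-fold. Of the genes called, 688 higher and 1130 lower were shared with day 9, where 210.2 and 359.62 would be by chance. The count was 2108 without cotton seed hulls day 16 replicate 1 and 2148 without wheat bran day 16 replicate 2, and library size alone gave 5848 higher and 625 lower, with 6541 and 6624 genes in limma on RPKM plus 1 and plus 0.1.

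Days 16 and 9 were compared on each substrate to follow the response over time. On spruce cellulose, pectin and mannan enzymes rose. Cellobiohydrolase II went from 6.44 ± 0.96 to 416 ± 30.1 RPKM (log2 fold change 5.99 ± 0.20, adjusted p = 1.4e-11) and xylanase C from 2.02 ± 0.476 to 140.1 ± 0.583 (6.10 ± 0.14). Cellobiohydrolases had 5 of 6 members rising and 1 falling (median 4.19, adjusted p = 4.93e-17, estimated 0.0125). Lytic polysaccharide monooxygenases had 3 of 3 members rising (median 4.29, adjusted p = 2.05e-13, estimated 0.0125). Endoglucanases had 8 of 10 members rising (median 3.21, adjusted p = 2.41e-19, estimated 0.00203). Pectinases had 9 of 10 members rising (median 2.60, adjusted p = 4.07e-12, estimated 0.0125). Mannanases had 3 of 3 members rising (median 0.53, adjusted p = 2.4e-06, estimated 0.021, highest 0.0257). An alpha-amylase (DICSQDRAFT_84199), which breaks down starch, rose (2.78 ± 0.10).

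The laccase and proteasome lists fell on spruce. Laccase B went from 1806 ± 979 to 169 ± 6.7 RPKM (-3.43 ± 0.35), and the manganese peroxidase DICSQDRAFT_59877 fell as well (-2.91 ± 0.27). Laccases and multicopper oxidases had 2 of 12 members rising and 6 falling (median -1.43, adjusted p = 0.0163, estimated 0.316). Proteasome genes had 17 of 17 members falling (median -0.88, adjusted p = 2.09e-10, estimated 0.0407). Glyceraldehyde-3-phosphate dehydrogenase (DICSQDRAFT_183206) fell too (-1.75 ± 0.11). The small heat shock protein DICSQDRAFT_109568 rose (2.26 ± 0.26) and ammonium transporter DICSQDRAFT_112666 fell (-2.00 ± 0.09). Glycolysis genes with 3 of 24 rising and 14 falling (list alone 3 rising and 15 falling), heat shock proteins and chaperones with 2 of 25 rising and 12 falling (list alone 2 rising and 13 falling), nitrogen uptake with 3 of 8 rising and 5 falling, peptide and amino acid transport with 7 of 39 rising and 20 falling, and housekeeping genes with 3 of 37 rising and 18 falling also passed. So did sugar transporters with 60 of 149 rising and 31 falling, lipases and esterases with 16 of 32 rising and 10 falling (list alone 16 rising and 11 falling), amylases with 5 of 10 rising and 4 falling, and xylan side-chain enzymes with 5 of 8 rising and 1 falling (list alone 5 rising and 2 falling). Across these 9 lists medians ran from -0.82 to 1.15 and adjusted p from 0.000222 to 0.0482, estimated 0.118 to 0.447, highest 0.789. Housekeeping genes are actin, tubulin, elongation factor and ubiquitin-conjugating enzymes. The call of amylases was lost without spruce day 9 replicate 1 (adjusted p = 0.0682). The call of sugar transporters was lost without spruce day 9 replicate 2 (adjusted p = 0.0593). The call of heat shock proteins and chaperones was lost without spruce day 9 replicate 2 (adjusted p = 0.0515). The call of nitrogen uptake was lost without spruce day 16 replicate 1 (adjusted p = 0.0574) and spruce day 16 replicate 2 (0.085), with adjusted p from 1.52e-05 to 0.498 over all alternatives of these 4 lists. On spruce 5354 genes passed the threshold, 2501 higher and 2853 lower, and 1614 of them were at least 2-fold.

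**Figure D2:**
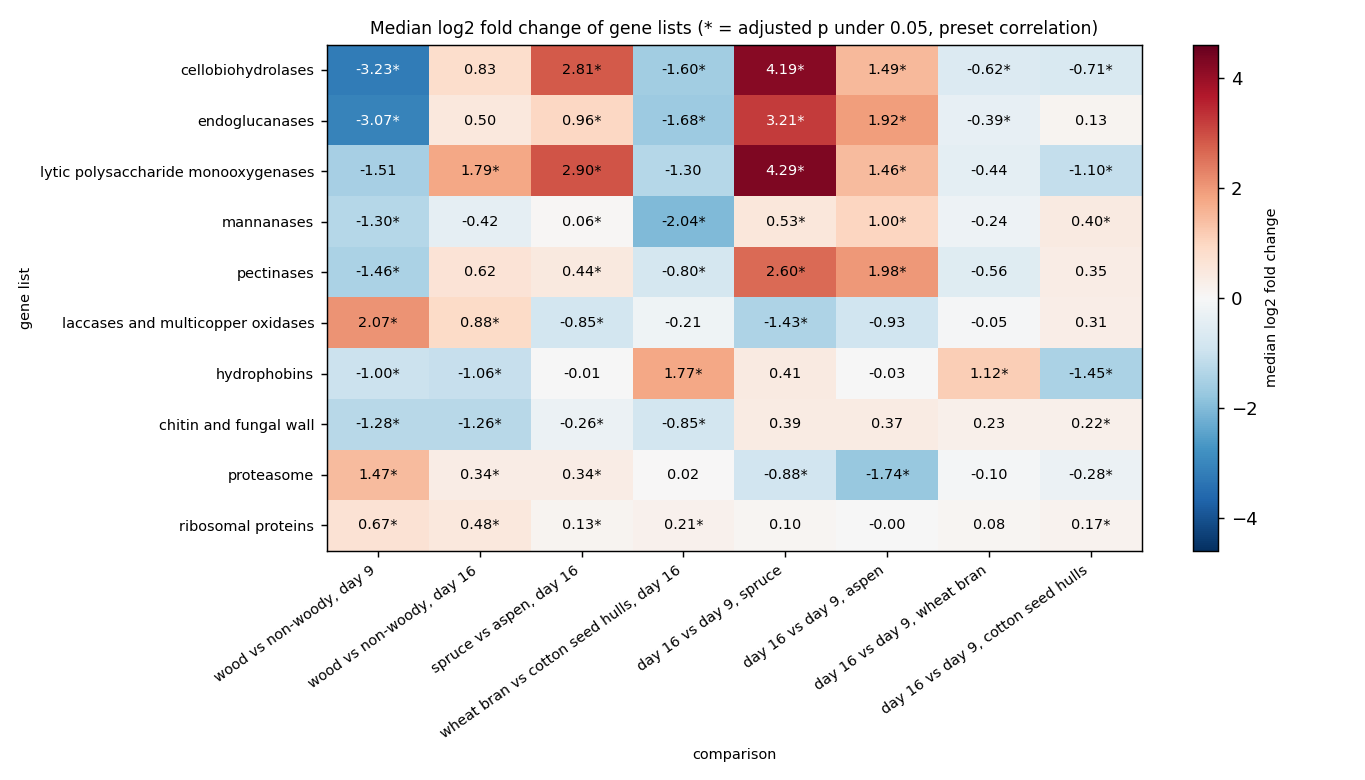
Median log2 fold change of 10 gene lists in 8 comparisons as a heat map, where an asterisk marks an adjusted p under 0.05 with the preset correlation. Cellobiohydrolases range from -3.23 for wood against non-woody substrates on day 9 to 4.19 for the day effect on spruce, and on cotton seed hulls the day effects of chitin and fungal wall enzymes and of ribosomal proteins change sign with library size alone.

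On aspen these lists rose too. Cellobiohydrolase II went from 3.13 ± 0.0979 to 62.9 ± 18.1 RPKM (log2 fold change 4.18 ± 0.22, adjusted p = 6.13e-10). Mannanases with 3 of 3 rising, lytic polysaccharide monooxygenases with 3 of 3 rising, and cellobiohydrolases with 4 of 6 rising and 1 falling (list alone 5 rising and 1 falling) passed. So did endoglucanases with 8 of 10 rising and 1 falling and pectinases with 8 of 10 rising and 1 falling. Across these 5 lists medians ran from 1 to 1.98 and adjusted p from 2.57e-05 to 0.0406, estimated 0.0513 to 0.325. The secreted lipase DICSQDRAFT_137620 rose (5.08 ± 0.23).

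Proteasome genes fell on aspen and had 17 of 17 members falling (median -1.74, adjusted p = 2.15e-19, estimated 0.0125). Heat shock protein HSS1 (DICSQDRAFT_97767) fell by 2.33 on the log2 scale. Heat shock proteins and chaperones with 2 of 25 rising and 20 falling and glycolysis genes with 3 of 24 rising and 15 falling also passed. So did lipases and esterases with 13 of 32 rising and 11 falling and sugar transporters with 71 of 149 rising and 39 falling (list alone 71 rising and 40 falling). Across these 4 lists medians ran from -1.11 to 0.39 and adjusted p from 0.000451 to 0.00906, estimated 0.0997 to 0.391. The call of lytic polysaccharide monooxygenases was lost without aspen day 9 replicate 1 (adjusted p = 0.0699), aspen day 9 replicate 2 (0.0645) and aspen day 16 replicate 1 (0.0681), with adjusted p from 3.53e-05 to 0.325 over all alternatives of this list. The manganese peroxidase DICSQDRAFT_59877 went from 575 ± 207 to 13.3 ± 0.181 RPKM (-5.59 ± 0.28). The nitroreductase DICSQDRAFT_69755 (-8.78 ± 1.18) and UbiA prenyltransferase DICSQDRAFT_81420 (-7.24 ± 0.86) fell as well. On aspen 6728 genes passed the threshold, 3331 higher and 3397 lower, and 2918 of them were at least 2-fold. Spruce and aspen shared 2016 genes that rose and 2326 that fell, where 787.12 and 915.69 would be by chance, and 111 changed in opposite directions.

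On wheat bran hydrophobins rose with time. DICSQDRAFT_54466 went from 189 ± 44.6 to 2355 ± 114 RPKM (log2 fold change 3.65 ± 0.20, adjusted p = 3.8e-07), with hydrophobin-315 at 2.23 ± 0.10. Hydrophobins had 7 of 15 members rising (list alone 9 rising, median 1.12, adjusted p = 1.9e-15, estimated 0.00483). A lipase (DICSQDRAFT_174841) rose (3.19 ± 0.33), and cellobiohydrolase II fell (-1.17 ± 0.15). Lipases and esterases with 14 of 32 rising and 2 falling (list alone 14 rising and 3 falling), fatty acid oxidation with 4 of 13 rising (list alone 5 rising), and cellobiohydrolases with 4 of 6 falling also passed. So did endoglucanases with 1 of 10 rising and 3 falling (list alone 2 rising and 7 falling) and oxalate and formate enzymes with 3 of 8 falling (list alone 1 rising and 3 falling). Across these 5 lists medians ran from -0.62 to 0.32 and adjusted p from 0.000137 to 0.0406, estimated 0.117 to 0.27, highest 0.363. The call of endoglucanases was lost without wheat bran day 9 replicate 1 (adjusted p = 0.0588) and wheat bran day 16 replicate 2 (0.125). The call of fatty acid oxidation was lost without wheat bran day 9 replicate 2 (adjusted p = 0.0562) and wheat bran day 16 replicate 2 (0.105), with adjusted p from 0.001 to 0.363 over all alternatives of these 2 lists. The formate dehydrogenase DICSQDRAFT_51840, which oxidises formate to carbon dioxide, went from 5918 ± 189 to 2412 ± 21.1 RPKM (-1.28 ± 0.11). A WSC-domain protein (DICSQDRAFT_146435) was lower on day 16 114-fold by reads (counting interval 48.5 to 352).

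On wheat bran 1830 genes passed the threshold, 966 higher and 864 lower, and 447 of them were at least 2-fold. The count was 878 to 1132 without any 1 of the 4 libraries of wheat bran and 3190 in a fit of only the compared groups.

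On cotton seed hulls hydrophobins fell with time. DICSQDRAFT_55052 went from 176 ± 0.281 to 11.7 ± 0.944 RPKM (log2 fold change -3.66 ± 0.52, adjusted p = 0.000875). Hydrophobins had 1 of 15 members rising and 8 falling (list alone 2 rising and 8 falling, median -1.45, adjusted p = 1.02e-06, estimated 0.03, highest 0.0335). A manganese-dependent peroxidase (DICSQDRAFT_50355) fell from 121 ± 1.47 to 4 ± 0.861 RPKM (-4.66 ± 0.50). Lytic polysaccharide monooxygenases with 2 of 3 falling, cellobiohydrolases with 1 of 6 rising and 4 falling, and mannanases with 2 of 3 rising also passed. So did proteasome genes with 8 of 17 falling (list alone 10 falling) and DNA replication and histone genes with 5 of 9 falling. Across these 5 lists medians ran from -1.10 to 0.40 and adjusted p from 0.00346 to 0.0174, estimated 0.0782 to 0.402. A multicopper oxidase (DICSQDRAFT_180464, 2.10 ± 0.13) and a GMC oxidoreductase (DICSQDRAFT_138769, 2.54 ± 0.16) rose. Reads of the undescribed gene DICSQDRAFT_124697 fell to 0 on day 16, at least 21.2-fold lower than on day 9.

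Amylases with 5 of 10 rising (list alone 6 rising), lipases and esterases with 13 of 32 rising and 2 falling, and chitin and fungal wall enzymes with 10 of 21 rising and 1 falling (list alone 11 rising and 2 falling) and a median of 0.22, or -0.026 by library size alone, also passed. So did sugar transporters with 37 of 149 rising and 13 falling (list alone 38 rising and 13 falling) and a median of 0.20, or -0.049 by library size alone, and ribosomal proteins with 25 of 92 rising and a median of 0.17, or -0.08 by library size alone. Across these 5 lists medians ran from 0.17 to 0.38 and adjusted p from 0.00177 to 0.0421, estimated 0.185 to 0.636, highest 0.753. The call of ribosomal proteins was lost with library size alone (adjusted p = 0.403), without cotton seed hulls day 16 replicate 1 (0.115) and cotton seed hulls day 9 replicate 1 (0.103). The call of sugar transporters was lost without cotton seed hulls day 16 replicate 2 (adjusted p = 0.0713) and cotton seed hulls day 9 replicate 2 (0.0777), with adjusted p from 0.00324 to 0.753 over all alternatives of these 2 lists. On cotton seed hulls 3004 genes passed the threshold, 1660 higher and 1344 lower, and 656 of them were at least 2-fold. The count was 1799 without cotton seed hulls day 16 replicate 1 and 1798 without cotton seed hulls day 9 replicate 2, and library size alone gave 760 higher and 3024 lower.

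Day effects were compared directly between substrates. Between wood and non-woody substrates, 5585 genes passed the threshold, 2658 higher and 2927 lower, and 1992 of them were at least 2-fold. Between spruce and aspen, 2013 genes passed the threshold, 1143 higher and 870 lower, and 787 of them were at least 2-fold. Between wheat bran and cotton seed hulls, 994 genes passed the threshold, 454 higher and 540 lower, and 390 of them were at least 2-fold. Library size alone gave 1358 higher and 270 lower. The count as reported became 538 to 647 without any 1 of the 8 libraries of wheat bran and cotton seed hulls. A fit of only the compared groups gave 967 between spruce and aspen and 2274 between wheat bran and cotton seed hulls.

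Lists that passed no test are given for wood against non-woody substrates on day 9. Beta-glucosidases, which split cellobiose, had 1 of 6 members higher and 3 lower (list alone 1 higher and 2 lower, median -0.14, adjusted p = 0.419). Glutathione S-transferases had 6 of 16 members higher and 2 lower (median 0.28, adjusted p = 0.73). Pentose catabolism had 1 of 3 members higher and 2 lower (median -0.39, adjusted p = 0.719), and the glyoxylate cycle, with a 2-isopropylmalate synthase among its members by name, 2 of 4 members higher and 2 lower (median -0.01, adjusted p = 0.83). Of the lists too small to test, other peroxidases had 1 of 2 members higher and 1 lower, xylanases 1 of 2 members lower, and cellobiose dehydrogenase 1 of 1 members lower.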

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

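The tests of summed hydrophobin RPKM, a single wood library and splits keeping replicates together were chosen after their result was seen, the others before. The patterns tested were already known. The results below drew attention because the change from day 9 to day 16 differed between substrates by a direct test. Genes with such differences numbered 5585 between wood and non-woody substrates, 2013 between spruce and aspen, and 994 between wheat bran and cotton seed hulls.

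Cellulose and pectin enzymes and proteasome genes took a different course on wood than on the non-woody substrates. Each list median is followed, in parentheses, by its adjusted p, that with an estimated correlation and, where above both, the highest over all alternatives. For the day effect on wood minus that on non-woody substrates the medians were 4.53 for cellobiohydrolases (1.74e-16, 0.0138), 3.33 for lytic polysaccharide monooxygenases (4.08e-07, 0.0402), 3.10 for endoglucanases (1.31e-13, 0.00297), 2.14 for pectinases (3.44e-10, 0.0205), 1.47 for xylan side-chain enzymes (0.00201, 0.0637, 0.34) and 0.56 for mannanases (3.6e-05, 0.0298, 0.0873). They were 0.20 for lipases and esterases (0.0235, 0.316, 0.553), 0.12 for sugar transporters (0.0343, 0.491), -0.77 for glycolysis genes (0.000242, 0.0733), -1.08 for heat shock proteins and chaperones (0.00106, 0.278), -1.13 for proteasome genes (1.81e-12, 0.03) and -1.30 for laccases and multicopper oxidases (0.016, 0.316). For spruce minus aspen they were 2.68 for lytic polysaccharide monooxygenases (1.02e-05, 0.06), 1.83 for cellobiohydrolases (6.88e-09, 0.0374), 0.87 for endoglucanases (0.00106, 0.0513), 0.76 for proteasome genes (9.8e-14, 0.0254), 0.48 for GMC oxidoreductases (0.0334, 0.123, 0.191) and -1.20 for copper radical oxidases (0.0172, 0.12, 0.165). Secreted proteases had a median of 0.00489, or -0.12 by library size alone (0.0235, 0.493). For wheat bran minus cotton seed hulls they were 2.50 for hydrophobins (2.4e-39, 0.00121), 0.17 for DNA replication and histone genes (0.00959, 0.423), 0.16 for copper radical oxidases (0.0343, 0.16, 0.2) and -0.39 for endoglucanases (0.0023, 0.0664). They were also -0.61 for oxalate and formate enzymes (0.0112, 0.166), -0.64 for pectinases (0.000779, 0.119) and -0.76 for mannanases (7.33e-06, 0.0219). Sugar transporters had a median of -0.24, or 0.000393 by library size alone (0.00769, 0.402). For wood minus non-woody substrates the call of sugar transporters was lost without replicate 2 of day 9 aspen or spruce. Adjusted p of this list ran from 0.00049 to 0.491 over all alternatives. For spruce minus aspen the call of GMC oxidoreductases was lost without aspen day 9 replicate 1 or spruce day 9 replicate 2. It was also lost without either aspen day 16 library. The call of secreted proteases was lost without aspen day 9 replicate 2 (adjusted p = 0.0734), aspen day 16 replicate 1 (0.0681) and spruce day 9 replicate 1 (0.16), with adjusted p from 0.000166 to 0.493 over all alternatives of these 2 lists. For wheat bran minus cotton seed hulls copper radical oxidases lost the call with library size alone (adjusted p = 0.0556). They also lost it without replicate 2 of wheat bran on day 9 or 16. Adjusted p ran from 0.000464 to 0.2 over all alternatives.

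Among the named genes 164 results differed. For wood minus non-woody substrates higher log2 values were found for DICSQDRAFT_136623 (6.64), DICSQDRAFT_152125 (6.11), DICSQDRAFT_166212 (5.76), DICSQDRAFT_157940 (5.76), DICSQDRAFT_96488 (5.75), DICSQDRAFT_181663 (5.32), DICSQDRAFT_133555 (5.30), DICSQDRAFT_59500 (4.72), DICSQDRAFT_132822 (4.69), DICSQDRAFT_105895 (4.58), DICSQDRAFT_172328 (4.41), DICSQDRAFT_162364 (4.37), DICSQDRAFT_152858 (4.36), DICSQDRAFT_124697 (4.33), DICSQDRAFT_170198 (3.83), DICSQDRAFT_157633 (3.72), DICSQDRAFT_181599 (3.60), DICSQDRAFT_109568 (3.48), DICSQDRAFT_137620 (3.48), DICSQDRAFT_108020 (3.33), DICSQDRAFT_154984 (2.69), DICSQDRAFT_50355 (2.68), DICSQDRAFT_134993 (2.61), DICSQDRAFT_141471 (2.59), DICSQDRAFT_131350 (2.57), DICSQDRAFT_84199 (2.55), DICSQDRAFT_94114 (2.49), DICSQDRAFT_51840 (2.17), DICSQDRAFT_65706 (2.01), DICSQDRAFT_167685 (2.003), DICSQDRAFT_86290 (1.86), DICSQDRAFT_146123 (1.85), DICSQDRAFT_149587 (1.80), DICSQDRAFT_103313 (1.48), DICSQDRAFT_88541 (1.40), DICSQDRAFT_107955 (1.35), DICSQDRAFT_91761 (1.14), DICSQDRAFT_71343 (1.04), DICSQDRAFT_167756 (0.93), DICSQDRAFT_133554 (0.93), DICSQDRAFT_130864 (0.92), DICSQDRAFT_54466 (0.85), DICSQDRAFT_82049 (0.74), DICSQDRAFT_143398 (0.71), DICSQDRAFT_94742 (0.71), DICSQDRAFT_47249 (0.55), DICSQDRAFT_110689 (0.45), DICSQDRAFT_154131 (0.42) and DICSQDRAFT_138257 (0.36). Lower values were found for DICSQDRAFT_69755 (-7.82), DICSQDRAFT_165026 (-7.74), DICSQDRAFT_81420 (-7.73), DICSQDRAFT_72440 (-7.31), DICSQDRAFT_161457 (-4.58), DICSQDRAFT_169869 (-4.50), DICSQDRAFT_144553 (-3.94), DICSQDRAFT_59877 (-3.59), DICSQDRAFT_111644 (-3.50), DICSQDRAFT_180719 (-3.02), DICSQDRAFT_138769 (-2.87), DICSQDRAFT_97767 (-2.50), DICSQDRAFT_176907 (-2.49), DICSQDRAFT_110823 (-2.48), DICSQDRAFT_66487 (-2.38), DICSQDRAFT_172714 (-2.10), DICSQDRAFT_163336 (-1.93), DICSQDRAFT_183166 (-1.85), DICSQDRAFT_172711 (-1.82), DICSQDRAFT_62584 (-1.76), DICSQDRAFT_183206 (-1.70), DICSQDRAFT_156959 (-1.58), DICSQDRAFT_147974 (-1.49), DICSQDRAFT_168992 (-1.43), DICSQDRAFT_112666 (-1.32), DICSQDRAFT_174841 (-1.27), DICSQDRAFT_170701 (-1.21), DICSQDRAFT_94193 (-1.15), DICSQDRAFT_96763 (-1.09), DICSQDRAFT_111318 (-1.05), DICSQDRAFT_113392 (-1.02), DICSQDRAFT_81391 (-0.85), DICSQDRAFT_69888 (-0.76), DICSQDRAFT_142470 (-0.70), DICSQDRAFT_108586 (-0.70), DICSQDRAFT_46769 (-0.55), DICSQDRAFT_135337 (-0.42) and DICSQDRAFT_131703 (-0.36). For spruce minus aspen the values above 0 were those of DICSQDRAFT_141931 (7.51), DICSQDRAFT_68823 (4.23), DICSQDRAFT_162938 (3.79), DICSQDRAFT_54693 (3.38), DICSQDRAFT_66487 (3.28), DICSQDRAFT_107932 (3.24), DICSQDRAFT_131122 (3.07), DICSQDRAFT_50737 (3.004), DICSQDRAFT_140533 (2.83), DICSQDRAFT_59877 (2.68), DICSQDRAFT_108020 (2.68), DICSQDRAFT_154984 (2.53), DICSQDRAFT_132822 (2.29), DICSQDRAFT_156505 (1.88), DICSQDRAFT_152125 (1.81), DICSQDRAFT_181663 (1.77), DICSQDRAFT_96488 (1.71), DICSQDRAFT_133555 (1.61), DICSQDRAFT_166212 (1.32), DICSQDRAFT_97767 (1.02), DICSQDRAFT_47249 (0.94), DICSQDRAFT_111318 (0.85), DICSQDRAFT_131172 (0.71) and DICSQDRAFT_113392 (0.70). Those below 0 were of DICSQDRAFT_170198 (-7.92), DICSQDRAFT_98769 (-6.36), DICSQDRAFT_182861 (-3.92), DICSQDRAFT_141471 (-3.91), DICSQDRAFT_157940 (-3.58), DICSQDRAFT_172726 (-3.52), DICSQDRAFT_59500 (-3.09), DICSQDRAFT_167685 (-3.03), DICSQDRAFT_155746 (-2.88), DICSQDRAFT_86709 (-2.82), DICSQDRAFT_157633 (-2.56), DICSQDRAFT_149587 (-2.16), DICSQDRAFT_71040 (-2.06), DICSQDRAFT_137620 (-2.02), DICSQDRAFT_181599 (-1.92), DICSQDRAFT_110823 (-1.87), DICSQDRAFT_162364 (-1.80), DICSQDRAFT_94114 (-1.12), DICSQDRAFT_140659 (-0.88), DICSQDRAFT_110689 (-0.87), DICSQDRAFT_71343 (-0.77), DICSQDRAFT_75292 (-0.75) and DICSQDRAFT_82049 (-0.57). For wheat bran minus cotton seed hulls values above 0 belonged to DICSQDRAFT_124697 (9.20), DICSQDRAFT_62768 (8.68), DICSQDRAFT_55052 (6.61), DICSQDRAFT_54466 (6.54), DICSQDRAFT_64881 (6.02), DICSQDRAFT_167756 (5.02), DICSQDRAFT_50355 (2.92), DICSQDRAFT_54693 (2.84), DICSQDRAFT_174841 (2.34), DICSQDRAFT_154984 (2), DICSQDRAFT_61994 (1.496), DICSQDRAFT_62584 (1.45) and DICSQDRAFT_167685 (0.99). Values below 0 belonged to DICSQDRAFT_182026 (-7.02), DICSQDRAFT_59213 (-3.06), DICSQDRAFT_156959 (-2.97), DICSQDRAFT_57684 (-2.58), DICSQDRAFT_88541 (-1.74), DICSQDRAFT_79806 (-1.73), DICSQDRAFT_143398 (-1.72), DICSQDRAFT_138769 (-1.70), DICSQDRAFT_180464 (-1.59), DICSQDRAFT_168992 (-1.57), DICSQDRAFT_86290 (-1.21), DICSQDRAFT_75292 (-1.18), DICSQDRAFT_51840 (-0.92), DICSQDRAFT_130864 (-0.78), DICSQDRAFT_132822 (-0.76), DICSQDRAFT_84199 (-0.57) and DICSQDRAFT_165065 (-0.53). Groups with at most 3 reads per library, where a fitted value depends on the prior count and is no bound, were part of the results of DICSQDRAFT_170198 and DICSQDRAFT_124697 in both of their tests, and of DICSQDRAFT_64881, DICSQDRAFT_59213, DICSQDRAFT_172328, DICSQDRAFT_180719, DICSQDRAFT_161457 and, for wood minus non-woody substrates, DICSQDRAFT_165026. Leaving out 1 library ended 33 of these calls, with adjusted p from 4.89e-22 to 1 over all their alternatives, where 1 stands for a change under 2-fold. The highest adjusted p of such an omission is given for each. For wood minus non-woody substrates it was that without wheat bran day 16 replicate 2 for DICSQDRAFT_165026 (0.487), without spruce day 9 replicate 1 for DICSQDRAFT_174841 (0.396) and DICSQDRAFT_170701 (0.0909), without cotton seed hulls day 16 replicate 1 for DICSQDRAFT_161457 (0.233) and DICSQDRAFT_66487 (0.0685), without aspen day 16 replicate 2 for DICSQDRAFT_167756 (0.163), without cotton seed hulls day 16 replicate 2 for DICSQDRAFT_172711 (0.134), without aspen day 9 replicate 1 for DICSQDRAFT_54466 (0.102), without wheat bran day 9 replicate 1 for DICSQDRAFT_133554 (0.0971), without wheat bran day 16 replicate 1 for DICSQDRAFT_72440 (0.0574) and without spruce day 9 replicate 2 for DICSQDRAFT_163336 (0.053). For spruce minus aspen it was that without aspen day 9 replicate 2 for DICSQDRAFT_154984 (0.254), DICSQDRAFT_97767 (0.182), DICSQDRAFT_166212 (0.139) and DICSQDRAFT_110823 (0.0822), without aspen day 16 replicate 1 for DICSQDRAFT_140659 (0.148), without aspen day 16 replicate 2 for DICSQDRAFT_82049 (0.133) and DICSQDRAFT_68823 (0.0697), without spruce day 16 replicate 2 for DICSQDRAFT_98769 (0.123), without spruce day 9 replicate 2 for DICSQDRAFT_172726 (0.0751), without aspen day 9 replicate 1 for DICSQDRAFT_156505 (0.0726) and without spruce day 16 replicate 1 for DICSQDRAFT_54693 (0.0715) and DICSQDRAFT_107932 (0.0677). For wheat bran minus cotton seed hulls it was that without cotton seed hulls day 16 replicate 1 for DICSQDRAFT_59213 (0.539), DICSQDRAFT_50355 (0.129) and DICSQDRAFT_84199 (0.064), without cotton seed hulls day 9 replicate 1 for DICSQDRAFT_64881 (0.46), DICSQDRAFT_88541 (0.143) and DICSQDRAFT_174841 (0.0946), without cotton seed hulls day 9 replicate 2 for DICSQDRAFT_165065 (0.184) and DICSQDRAFT_86290 (0.142) and without cotton seed hulls day 16 replicate 2 for DICSQDRAFT_54693 (0.135) and DICSQDRAFT_167685 (0.0809). Other alternatives than these and the 2-fold minimum ended 6 more: DICSQDRAFT_131703 (0.121) with library size alone for wood minus non-woody substrates, DICSQDRAFT_110689 (0.0835), DICSQDRAFT_94114 (0.0665) and DICSQDRAFT_141931 (0.0534) in a fit of only the compared groups for spruce minus aspen, DICSQDRAFT_132822 (0.0889) with limma on RPKM plus 0.1 for wheat bran minus cotton seed hulls, and DICSQDRAFT_130864 (0.0525) with limma on RPKM plus 1 for wheat bran minus cotton seed hulls.

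On day 9 the 28 called members of the cellobiohydrolases, endoglucanases, mannanases and pectinases had a median of -2.33 for wood against non-woody substrates, with 26 lower. Library composition stays open, as library size alone (-2.05) shifts all genes nearly alike. Medians of -2.36 to -2.29 without 1 library leave a single odd one open, as members were chosen with all 8. A candidate explanation is a delay, in which wood cultures move by day 16 toward the day 9 state of the non-woody cultures. Across genes the day effect on spruce correlated with the day 9 difference of non-woody substrates minus aspen (Pearson's r = 0.631), and that on aspen with non-woody substrates minus spruce (0.614), although genes are not independent. Both contrasts subtract a day 9 wood state, so any departure from that state would add to r, and substrate chemistry stays open and untested.

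Hydrophobins had a median day effect difference of 2.50 for wheat bran minus cotton seed hulls. Reads traded between similar hydrophobin genes are argued against by the summed RPKM, which went from 2064 ± 174 to 8245 ± 159.5 on wheat bran (ratio 3.995, n = 2) and from 4799 ± 55 to 2689 ± 81.3 on cotton seed hulls (ratio 0.56). A bias with gene length is argued against by the 882 other genes with models of 500 bases or fewer, as are 12 of the 15 hydrophobins, whose median was -0.0554. Leaving out 1 of the 8 libraries gave medians of 1.86 to 2.57, which argues against a single odd library. That hydrophobins follow the time course of each substrate is one hypothesis, and the state of the mycelium on day 16 was not tested.

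At least 16-fold higher on wood on day 9 were 140 genes, with a median of 5.13. A single wood library is argued against by 137 to 140 such genes when chosen again without 1 of the 4 wood libraries. Such genes may lie side by side in the genome: among the 10550 tested genes in the reference order, with scaffold borders inferred from falls in start position, they made 12 adjacent pairs, 6.51 times the mean of 10000 random sets of that size (1.84, highest 7). Joint regulation of neighbours and reads that run over from one gene into the next both stay open.

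In a fit of each day with only the sides as groups, 1 of the 35 splits of the 8 libraries, the real one, gave as many genes for wood against non-woody substrates on day 9 (5832, highest other 1). On day 16 it was again 1 split (4110, highest other 11). These libraries are replicate pairs of 4 substrates, and the 3 splits that keep replicates together are too few for such a test (1 and 1 of 3 with as many, highest other 0 and 11). For the difference of day effects the 3 pairings of the substrates are too few for such a test, with 5585 genes for the real pairing (1 of 3 with as many) and 1509 for the highest other.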

How the results depend on the processing

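The day 16 contrast of wood without the day 9 wood groups and the 7 further lists were added after the data were seen, and the other tests were chosen before. Counts of changed genes stayed within 1.5 times of the reported ones in all 13 comparisons under DESeq2 size factors, the DESeq2 Wald test, no filter on low counts (11410 genes) and the replicate block, and the added contrast gave 6832 genes. With the 2-fold minimum the counts fell to 2952 and 1665 for wood against non-woody substrates on days 9 and 16, 438 and 507 for spruce against aspen, and 817 and 847 for wheat bran against cotton seed hulls. They fell to 1614, 2918, 447 and 656 for the day effects on spruce, aspen, wheat bran and cotton seed hulls, and to 1992, 787 and 390 for their differences, because fewer genes reach that size. Library size alone gave 3510 for spruce against aspen on day 9, 6473 for wheat bran against cotton seed hulls on day 16 and 1628 for their difference of day effects. For these last 2, limma on RPKM gave 6541 and 1535 with 1 added and 6624 and 1610 with 0.1 added. Fitting only the compared groups gave fewer for spruce against aspen on day 9 (376), whose replicates spread most, and for spruce minus aspen (967). It gave more on wheat bran (3190) and for wheat bran minus cotton seed hulls (2274). With 1 library left out counts ran from 1290 to 2400 and from 1306 to 2042 for spruce against aspen on days 9 and 16, and from 2239 to 2532 and from 2108 to 2291 for wheat bran against cotton seed hulls. They ran from 878 to 1132 on wheat bran, from 1798 to 2178 on cotton seed hulls and from 538 to 647 for their difference, where 1 arm is left with 1 library. They ran from 7121 to 7439 and from 5726 to 5999 for wood against non-woody substrates, from 4288 to 4833 on spruce, from 6001 to 6161 on aspen, from 5138 to 5608 for wood minus non-woody substrates, and from 1357 to 2200 for spruce minus aspen. Genes called with RPKM not overlapping numbered 3497 for wood on day 16. Other pairings also called many genes, which points to differences between single substrates: spruce and wheat bran against aspen and cotton seed hulls gave 3657 on day 9 and 3335 on day 16, and spruce and cotton seed hulls against aspen and wheat bran gave 2221 and 2687. List calls numbered 34 with an estimated correlation and from 127 to 145 with 1 library left out. Without the most changed member they numbered 85, against 111 as reported in the 364 tests of lists of more than 3 members, to which this was limited. Fry, which tests against no change, passed 251, of which 123 had no call as reported. Except for the 2-fold minimum and the smaller lists, the cause was not tested.

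Of the results of named genes, D-galacturonic acid reductase DICSQDRAFT_130864 reversed on day 9 from -0.18 ± 0.07 for wood against non-woody substrates to 0.0918 with library size alone, and 0.0817 and 0.0824 with limma on RPKM plus 1 and plus 0.1, and the cause was not tested. Of 521 results of named genes, 94 fell under the 2-fold minimum, and 42 lost and 14 gained the call in the smaller fits. Lost and gained were 19 and 10 with library size alone, 17 and 9 with limma plus 1, and 21 and 9 with plus 0.1. Calls lost and gained were 3 and 2 with the Wald test and 240 and 12 over all omissions of 1 library, and 3 were lost with DESeq2 size factors, 4 without the filter and 4 with the replicate block. For lists, 4 calls were lost and 15 gained with library size alone, 37 and 18 with limma plus 1, 36 and 19 with plus 0.1, 6 and 13 in the smaller fits, and 45 and 73 over the omissions of 1 library. They were 1 and 2 with DESeq2 size factors, 2 and 6 with the Wald test, 6 and 11 without the filter, 4 and 3 with the replicate block, and 33 and 7 without the most changed member, while 94 were lost with an estimated correlation. Shares of lists in all reads instead of RPKM moved by more than 1 SD for 245 of 272 values, since RPKM divides by gene length. Depth limits the genes with few reads: 826 genes were left out by the filter, and small changes in them were not tested.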

Other observations

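The tests of the 7 further lists were chosen after the result was seen, and the neighbour search before its own result. Glycoside hydrolases with no family in the description and terpenoid synthases, which make the carbon skeletons of terpenes, also differed between groups. The word estimated stands before the adjusted p with an estimated correlation. Terpenoid synthases had 9 of 21 members lower (list alone 10 lower, median -0.75, adjusted p = 0.00149, estimated 0.13) for spruce against aspen on day 9, with DICSQDRAFT_80370 at -1.24 ± 0.10. The glycoside hydrolases had 4 of 47 members higher and 24 lower (list alone 7 higher and 25 lower, median -0.34, adjusted p = 0.00149, estimated 0.245) for wheat bran against cotton seed hulls on day 9. They also passed for these substrates on day 16 (median -0.48), with time on spruce (0.53) and on aspen (0.66), and for the day effect on wood minus that on non-woody substrates (0.47), with adjusted p from 2.87e-05 to 0.0406, estimated 0.13 to 0.406. These values are adjusted over the 91 tests of the added lists, and none passed with an estimated correlation. Acid proteases (32 tested), family S53 proteases (8), aldo/keto reductases (44), DnaJ-domain proteins (18) and clavaminate synthase-like proteins (38) passed in none of the 13 comparisons.

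Genes at least 16-fold higher on wood on day 9 included runs of neighbours in the gene order, chosen after their values were seen. Their adjusted p were at most 8.3e-06. A run of 6 held DICSQDRAFT_182370 (6.28 ± 0.14), norsolorinic acid reductase DICSQDRAFT_66487 (8.83 ± 0.34), cytochrome P450 DICSQDRAFT_172711 (7.77 ± 0.25), cytochrome P450 DICSQDRAFT_109788 (5.92 ± 0.12), HAD-like protein DICSQDRAFT_148930 (5.47 ± 0.18) and alpha/beta-hydrolase DICSQDRAFT_172714 (6.76 ± 0.18). A run of 3 held the sterol 14 alpha-demethylase DICSQDRAFT_147974 (6.42 ± 0.16), DICSQDRAFT_63210 (5.06 ± 0.12) and DICSQDRAFT_127802 (4.79 ± 0.16). The other 5 runs were pairs, of which those with a described gene were phosphoketolase DICSQDRAFT_178292 (4.92 ± 0.39) with DICSQDRAFT_133398 (4.69 ± 0.20) and cytochrome P450 DICSQDRAFT_160082 (4.65 ± 0.33) with UbiA prenyltransferase DICSQDRAFT_81420 (8.65 ± 0.75).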
